A study of Mus musculus with 10 samples.

How the data were processed

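RNA sequencing libraries of sorted mouse brain cells were analysed from the deposited table of counts, which per the labels come from the ischemic hemisphere of mice. Fluorescent cells were sorted without staining after enzymatic dissociation and Percoll separation, and the libraries were made with a template-switching kit for low RNA input followed by an unstranded library kit, from 1 or 5 ng of RNA with 9 or 11 cycles of PCR, for which the labels give no value per library. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, DESeq2 and the mouse genome build GRCm38. The counting program, its annotation and its strand setting are not given in the sources used here. The deposited values are whole-number counts per Ensembl gene for 28585 genes in 10 libraries, and the lowest total of a gene over all libraries was 2. Ribosomal protein genes held 0.175% to 0.305% of the counts in a library. Whether reads that map to several places were counted is not given in the sources used here, so CPM of genes with close paralogues, such as H2-Q and Klr genes, may lie below their true level. Symbols and coordinates were taken from GENCODE M21 on GRCm38, which held 28492 of the gene identifiers. The other 93 had no symbol, and 5 symbols were shared by 2 identifiers.

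Groups followed the labels and sample titles: 3 libraries of microglia, 3 of CD11c-eYFP+ cells of parabiotic wild type mice and 4 of CD11c-eYFP+ cells of Itgax-Venus mice. Replicate 15 of the parabiotic group was placed by its title and the age of the mouse, since its labels give neither cell type nor strain. Microglia and transgenic donors were 13 to 14 weeks old and parabiotic mice 15 to 16 weeks. The comparisons were parabiotic CD11c cells against microglia, transgenic CD11c cells against microglia, and transgenic against parabiotic CD11c cells. All 10 libraries entered one fit with one mean per group, so that the groups shared an estimate of the spread. Genes were filtered with filterByExpr by group, which kept 15151 and removed 13434, libraries were scaled with TMM, and each comparison was tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion (glmQLFit, glmQLFTest) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common dispersion was 0.1002, a biological coefficient of variation of 0.317. Libraries held between 31534625 and 41730688 counts, and the spread between replicates, more than counting error, set the precision. P-values measure the spread between these samples as labelled, while the intervals and floors given for genes at 0 to 3 counts cover counting error alone.

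30 gene lists for cell identities, immune pathways and other cell types, fixed before the data were examined, were tested with camera from limma 3.58.1 on log2 CPM at an inter-gene correlation of 0.01, adjusted over all lists and comparisons. 29 could be tested, and the haemoglobin list, with 1 tested member, was left out. Itgax and Cx3cr1 were left out of the lists because they carry the reporters. Counts are of tested members, each also adjusted over the list alone. Genes were named by a rule fixed before the data were examined: 50 genes named in advance, then for each comparison the 8 with the largest positive and the 8 with the largest negative log2 fold change past the threshold, with at least 20 CPM in the higher group, libraries that did not overlap between the groups and no predicted or clone symbol, then up to 3 members of each list in its main direction and up to 2 in the other. Not every gene of the list-based part or of those named in advance is printed. A gene at 0 in all libraries of a group was set against a floor of 3 counts over the group. The within-run values come from the same fit with a term for transgenic replicates 26 and 27, whose library numbers lie apart from those of the other 8. Levels of a list in percent are medians over its members of the CPM relative to a reference group, and exact permutation tests over all 35 splits compared list means between transgenic and parabiotic libraries. What shared microglia bring to both comparisons where no gene differs was estimated in 20 simulations of unchanged groups.

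The alternatives tried were RLE and upper quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter or a stricter one (at least 5 CPM in at least 3 libraries), only the 2 groups compared in the fit, a term for the library run, thinned counts, non-robust dispersion, a 2-fold minimum, fry, an estimated correlation in camera, other summaries of the percent levels, and each library left out in turn. edgeR was run on simulated data with the group sizes and dispersion of this series. It called 27, 20 and 31 of 100 genes changed 2-fold in the 3 comparisons in turn. It called 90, 81 and 89 of 100 changed 4-fold, and 6, 6 and 7 unchanged genes. Without any change edgeR called 0 genes, and camera called only the changed list. Simulated mixture shares erred by up to 0.55 percentage points. These runs do not test real lists of correlated genes. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Raw reads were not analysed.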

Results

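RNA of fluorescent cells sorted from the ischemic brain hemisphere of mice was sequenced, and the deposited gene counts of 10 libraries were analysed. 3 libraries held microglia, the resident phagocytes of the brain, from mice whose red reporter is switched on in cells that express the fractalkine receptor gene Cx3cr1. Another 3 held CD11c-eYFP+ cells of wild type mice that had been joined by parabiosis, a surgically shared circulation, to a partner with the Itgax-Venus reporter, a yellow fluorescent protein under the control of the CD11c gene Itgax. Cells of this group, called parabiotic CD11c cells here, carry the reporter of the partner and so derive, by the design, from the shared circulation. The last 4 libraries held CD11c-eYFP+ cells of Itgax-Venus mice themselves, called transgenic CD11c cells. Parabiotic replicate 15 lacked cell type and strain labels and was placed by title and age. Library totals were 33605252, 31534625 and 32111625 counts in microglia replicates 39, 40 and 41, and 35129008, 33229181 and 34304338 in parabiotic replicates 3, 11 and 15. In transgenic replicates 23, 24, 26 and 27 they were 34982960, 36393444, 41211278 and 41730688. Between 20312 and 22165 genes had a count in a library.

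Levels below are TMM-scaled CPM, as mean ± SD over 3 microglia, 3 parabiotic and 4 transgenic libraries, and fold changes are log2 values ± SE from edgeR quasi-likelihood fits with Benjamini-Hochberg adjusted p. Itgax, which drives the sort reporter, stood at 44.4 ± 18.9 CPM in microglia, 504 ± 54.3 in parabiotic and 224 ± 126 in transgenic CD11c cells. Cx3cr1, which carries the Cre knock-in of the microglia donors, stood at 1739 ± 143, 596 ± 203 and 1709 ± 1058 CPM. The most abundant transcript was that of the lysosomal protease Ctsd in microglia, that of the lipid carrier Apoe in the parabiotic libraries and in transgenic replicates 23 and 24, and that of Spp1 (osteopontin) in transgenic replicates 26 and 27. Along the first dimension of a multidimensional scaling plot (59.3% of the variance) the microglia libraries lay between -3.04 and -2.94, the transgenic libraries between -0.63 and 0.69 and the parabiotic libraries between 2.74 and 3.06. Transgenic replicates 26 and 27 carried library numbers apart from the consecutive run of the other 8 libraries. Between replicates 23 and 24 the chi-square per degree of freedom was 16.8, while the other pairs of transgenic libraries reached 240 to 304, against 39.1 to 102 between microglia and 30.6 to 48.7 between parabiotic libraries. Comparisons of the transgenic group also give values within the run, from a fit with a run term. There its mean rests on replicates 23 and 24 alone.

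The first comparison set infiltrating parabiotic CD11c cells against microglia and addresses the question of the series design, which genes are specific to each population. Genes of dendritic cells, of antigen presentation on MHC class II and of monocytes were higher in parabiotic CD11c cells, and genes of homeostatic microglia, of the cell cycle and of several inflammatory cytokines were lower. With an estimated correlation none of these lists passed (adjusted p = 0.13 to 0.531). Flt3, the receptor of a growth factor that dendritic cells need, stood at 143 ± 16.6 CPM against 1.3 ± 0.658 in microglia (log2 fold change 6.78 ± 0.71, adjusted p = 4.19e-05). The MHC class II chain H2-Aa reached 5745 ± 728 against 31.7 ± 10.6 CPM (7.50 ± 0.55, adjusted p = 5.98e-06). Sall1, a transcription factor of microglial identity, fell from 387 ± 75.3 to 0.268 ± 0.122 CPM (-10.47 ± 0.79, adjusted p = 6.43e-06), and the cytokine gene Tnf from 835 ± 199.7 to 27 ± 8.42 CPM (-4.95 ± 0.32, adjusted p = 3.27e-06).

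Of the core genes of conventional dendritic cells, 23 of 25 members were higher, 1 was lower and 1 was not called. 23 were higher and 1 was lower adjusted over the list alone (camera adjusted p = 1.82e-20, adjusted p = 0.201 with an estimated correlation). The calls with the lowest p were the aspartic protease Napsa (9.51 ± 0.56), the adhesion receptor Slamf7 (5.71 ± 0.40) and the lysophospholipid receptor P2ry10 (9.66 ± 0.77), and the transcription factor Zbtb46 stood at 2.06 ± 0.55, while the chromatin protein Hmgn3 was the lower member (-1.01 ± 0.33). For the cross-presenting cDC1 subset, 9 of 20 members were higher, 3 were lower and 8 were not called. 9 were higher and 3 were lower adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.531 with an estimated correlation). Xcr1, its chemokine receptor, was at 3.58 ± 0.70 and Clec9a, its receptor for dead cells, at 5.27 ± 0.98, whereas the cDC1 factor Irf8 was lower (-0.58 ± 0.17) and Batf3 was not called (0.03 ± 0.41). For the cDC2 subset, 12 of 20 members were higher, 1 was lower and 7 were not called. 13 were higher and 1 was lower adjusted over the list alone (camera adjusted p = 6.64e-05, adjusted p = 0.387 with an estimated correlation), with Cd209a at 6.73 ± 1.06, and Irf4 at 2.31 ± 0.68, while Sirpa, which microglia also express, was lower (-0.75 ± 0.25). Among genes of dendritic cell maturation and migration, 14 of 23 members were higher, 5 were lower and 4 were not called. 14 were higher and 5 were lower adjusted over the list alone (camera adjusted p = 0.000661, adjusted p = 0.389 with an estimated correlation). The lymph node homing receptor Ccr7 (6.61 ± 0.79) and the chemokine Ccl22 (5.31 ± 0.48) were higher, while the actin bundler Fscn1 (-2.26 ± 0.53) and the activation marker Cd83 (-1.51 ± 0.19) were lower. Left out singly, libraries ended the calls of Sirpa (replicates 3, 11, 15, 39, 40 or 41, adjusted p = 0.0735 to 0.12), Irf8 (replicates 3, 11, 40 or 41, adjusted p = 0.0573 to 0.105), Irf4 (replicates 3, 40 or 41, adjusted p = 0.0674 to 0.0795), Hmgn3 (replicates 11, 15, 39, 40 or 41, adjusted p = 0.053 to 0.116) and Zbtb46 (replicates 40 or 41, adjusted p = 0.0538 to 0.0573).

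In the MHC class II pathway, 11 of 13 members were higher, 0 were lower and 2 were not called. 11 were higher adjusted over the list alone (camera adjusted p = 1.59e-11, adjusted p = 0.201 with an estimated correlation). Cd74, the invariant chain, reached 15940 ± 1827 CPM against 177 ± 34.4 (6.49 ± 0.55, adjusted p = 1.27e-05), the transactivator Ciita stood at 7.45 ± 0.91 and the lysosomal thiol reductase Ifi30 at 1.17 ± 0.17. The MHC class I pathway did not pass the list test (1 higher, 4 lower and 15 not called of 20, camera adjusted p = 0.371). 3 were lower and 1 was higher adjusted over the list alone, with the nonclassical H2-Q6 at -2.10 ± 0.40 and the immunoproteasome subunit Psmb8 at 0.72 ± 0.19. With 1 library left out the call ended for Psmb8 (replicates 15, 39 or 40, adjusted p = 0.0619 to 0.0897). Monocyte genes were higher as a group, as 16 of 20 members were higher, 0 were lower and 4 were not called. 17 were higher adjusted over the list alone (camera adjusted p = 1.41e-14, adjusted p = 0.13 with an estimated correlation). Among them Ly6c2, a marker of inflammatory monocytes, was at 7.78 ± 0.57 and Ccr2, which guides them out of the marrow, at 6.76 ± 0.53. Chemokine receptor and adhesion genes rose too, since 13 of 23 members were higher, 3 were lower and 7 were not called. 14 were higher and 3 were lower adjusted over the list alone (camera adjusted p = 8.42e-05, adjusted p = 0.251 with an estimated correlation), led by Ccr2, the gut homing integrin Itgb7 (7.93 ± 0.77) and Cxcr4 (3.74 ± 0.38), with the adhesion molecule Icam1 lower (-2.87 ± 0.23). Of the natural killer cell list only 4 of 12 members could be tested, of which 3 were higher, 0 were lower and 1 was not called. 3 were higher adjusted over the list alone (camera adjusted p = 0.00116, adjusted p = 0.209 with an estimated correlation). The members were the lectin receptors Klrk1 (7.91 ± 0.68), Klrd1 (7.18 ± 0.74) and Klre1 (4.55 ± 1.11).

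Among homeostatic microglial genes, 27 of 28 members were lower, 0 were higher and 1 was not called. 27 were lower adjusted over the list alone (camera adjusted p = 1.86e-27, adjusted p = 0.201 with an estimated correlation). The purinergic receptor P2ry12 fell from 1890 ± 269.7 to 70.3 ± 8.32 CPM (-4.75 ± 0.31), Tmem119 was at -3.01 ± 0.38 and the growth factor receptor Csf1r at -2.36 ± 0.26. Of the cell cycle genes, 25 of 28 members were lower, 0 were higher and 3 were not called. 27 were lower adjusted over the list alone (camera adjusted p = 4.42e-10, adjusted p = 0.389 with an estimated correlation). Mki67, a marker of cycling cells, stood at 17.9 ± 0.475 against 109.8 ± 33.8 CPM (-2.62 ± 0.27), and the mitotic genes Kif11 and Plk1 at -2.52 ± 0.36 and -3.30 ± 0.50. In the cytokine and chemokine list, 21 of 41 members were lower, 7 were higher and 13 were not called. 22 were lower and 7 were higher adjusted over the list alone (camera adjusted p = 6.39e-05, adjusted p = 0.205 with an estimated correlation). Il1a (-4.72 ± 0.22), Tnf and the chemokines Ccl4 (-4.15 ± 0.30) and Ccl3 (-3.08 ± 0.23) were lower, whereas Il1b (1.20 ± 0.23) and Cxcl16 (1.06 ± 0.18) were higher. Interferon response genes were lower, as 15 of 24 members were lower, 0 were higher and 9 were not called. 21 were lower adjusted over the list alone (camera adjusted p = 3.98e-05, adjusted p = 0.501 with an estimated correlation), among them the chemokine Cxcl10 (-4.33 ± 0.62), the RNA sensor Ifih1 (-1.29 ± 0.18) and Ifi27l2a (-2.82 ± 0.35). Immediate early genes, which tissue dissociation is known to induce, were also lower, since 11 of 22 members were lower, 1 was higher and 10 were not called. 11 were lower and 1 was higher adjusted over the list alone (camera adjusted p = 0.00202, adjusted p = 0.393 with an estimated correlation), with Egr1 at -4.32 ± 0.41.

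Complement and phagocytosis genes had a lower list value, as 13 of 29 members were lower, 3 were higher and 13 were not called. 13 were lower and 3 were higher adjusted over the list alone (camera adjusted p = 0.00746, adjusted p = 0.356 with an estimated correlation). The bridging protein gene Pros1 (-2.87 ± 0.18) and the complement gene C4b (-3.65 ± 0.31) were lower, and the complement regulator Cfp (properdin) was higher (5.09 ± 0.50). Lipid handling genes were higher, as 10 of 23 members were higher, 2 were lower and 11 were not called. 10 were higher and 2 were lower adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.205 with an estimated correlation). The members with the lowest p were the nuclear receptor Nr1h3 (3.41 ± 0.36), the acid lipase Lipa (2.28 ± 0.24) and the fatty acid sensor Pparg (4.74 ± 0.55), while the cholesterol hydroxylase Ch25h was lower (-6.58 ± 0.73). The damage-associated microglia list went both ways (5 higher, 7 lower and 12 not called of 24, camera adjusted p = 0.314). 7 were lower and 5 were higher adjusted over the list alone, with the glycoprotein Gpnmb at 7286 ± 686 against 90.5 ± 85.2 CPM (6.33 ± 0.87), Clec7a at 1.53 ± 0.24, Apoe at 2.03 ± 0.31, Csf1 at -5.98 ± 0.45 and Cst7 at -3.14 ± 0.46. Spp1 (0.49 ± 0.65) and Igf1 (-1.08 ± 0.79) were not called. Toll-like receptor genes did not pass as a list (3 higher, 8 lower and 9 not called of 20, camera adjusted p = 0.239). 9 were lower and 3 were higher adjusted over the list alone, with Tlr7 at -1.84 ± 0.20 and Tlr8 at 3.36 ± 0.23. Neither did TGF-beta signalling (4 higher, 9 lower and 7 not called of 20, camera adjusted p = 0.341). 10 were lower and 4 were higher adjusted over the list alone, with Smad3 at -2.40 ± 0.31. Glycolysis and hypoxia genes were not called (4 higher, 4 lower and 14 not called of 22, camera adjusted p = 0.733). 5 were lower and 4 were higher adjusted over the list alone. The phosphofructokinase Pfkp was at 4.25 ± 0.46 and the angiogenic factor Vegfa at 4.12 ± 0.77. The macrophage list had a median of -0.13 and a mean of 0.09, with a test that leaned upward (6 higher, 6 lower and 8 not called of 20, camera adjusted p = 0.255). 6 were higher and 6 were lower adjusted over the list alone. The lysozyme gene Lyz2 was at 3.79 ± 0.22. Plasmacytoid dendritic cell genes did not pass (6 higher, 3 lower and 3 not called of 12, camera adjusted p = 0.492). 6 were higher and 3 were lower adjusted over the list alone.

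Markers of other cell types were measured the same way. Neutrophil genes were higher as a list, as 6 of 8 members were higher, 1 was lower and 1 was not called. 7 were higher and 1 was lower adjusted over the list alone (camera adjusted p = 0.00746, adjusted p = 0.355 with an estimated correlation). The alarmin gene S100a8 stood at 5.05 CPM in parabiotic replicate 3, 202 in replicate 11 and 23.2 in replicate 15, and 0.109 ± 0.0671 in microglia. Without transgenic replicate 27 in the fit the neutrophil list gave camera adjusted p = 0.0528. Astrocyte genes were lower, as 3 of 9 members were lower, 0 were higher and 6 were not called. 3 were lower adjusted over the list alone (camera adjusted p = 0.0302, adjusted p = 0.467 with an estimated correlation, adjusted p = 0.0687 within the run with 3 members lower, which ended the call), with the intermediate filament gene Gfap at 1.59 ± 0.112 against 17 ± 6.7 CPM. Neuronal genes were lower as well, as 5 of 5 members were lower, 0 were higher and 0 were not called. 5 were lower adjusted over the list alone (camera adjusted p = 0.00503, adjusted p = 0.201 with an estimated correlation), all at or below 2.11 CPM on average. T cell genes had no call (edgeR called 0 of 5, with 1 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.356). B cell genes did not pass (3 higher, 0 lower and 5 not called of 8, camera adjusted p = 0.0987). 3 were higher adjusted over the list alone. Nor did oligodendrocyte genes (1 higher, 1 lower and 6 not called of 8, camera adjusted p = 0.368). 1 was higher and 1 was lower adjusted over the list alone. Endothelial genes were not called either (0 higher, 1 lower and 9 not called of 10, camera adjusted p = 0.34). 1 was lower adjusted over the list alone. Of the haemoglobin list only Hbb-bs could be tested, at 0.0422 CPM in microglia, 1.21 in parabiotic and 1.46 in transgenic CD11c cells.

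In each comparison the genes with the largest changes were taken only from those whose libraries did not overlap between the groups. The serotonin receptor gene Htr7 (chromosome 19, 35958734 to 36057507) had no count in microglia and 36.3 ± 10.8 CPM in parabiotic CD11c cells, at least 1205-fold higher against a floor of 3 counts over the microglia group. The immunoglobulin A heavy chain gene Igha had 1 count in all microglia libraries, a ratio of 6403 (95% counting interval 1149 to 252900), and Fam83f also 1 count, a ratio of 2806 (503 to 110900). The others were E-cadherin, Cdh1 (chromosome 8, 106603351 to 106670246, 10.89 ± 1.01), the chitinase-like Chil3 (10.63 ± 1.49), coagulation factor F7 (chromosome 8, 13026034 to 13035809, 10.19 ± 0.45), the glycosphingolipid enzyme B3gnt5 (10.12 ± 1.22) and the immunoglobulin light chain Igkc (10.04 ± 0.90). At the lower end, the homeobox gene Prox1 (chromosome 1, 190118035 to 190170714) had no count in parabiotic CD11c cells and 22.9 ± 7.34 CPM in microglia, at least 769-fold lower. The potassium channel Kcnma1 had 2 counts in the parabiotic group, with a ratio of 1162 in favour of microglia (321 to 9604). Sall1 (chromosome 8, 89027235 to 89044162) and its relative Sall3 (-9.84 ± 0.63) followed, with the membrane protein Tmc7 (-9.59 ± 0.61), the synuclein partner Sncaip (-8.98 ± 0.83), the phospholipid flippase Atp8a2 (-8.81 ± 0.91) and the crystallin Crybb1 (-8.77 ± 0.76).

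In all, 5347 of 15151 tested genes (35.3%) differed between parabiotic CD11c cells and microglia, 2633 higher and 2714 lower, and 3837 of them by at least 2-fold. The count became 8334 without both transgenic libraries of the other run. The libraries of the 2 groups did not overlap for 60.3% of tested genes, where chance gives 10%. Of the 29 lists tested, 18 passed, 10 higher and 8 lower (17 with the run term, 10 higher and 7 lower). With an estimated correlation camera called 0 lists (7 at an unadjusted p under 0.05, lowest adjusted p = 0.130), and fry, which asks whether a list's genes move on balance one way, called 21. The age of the mice differed between the groups, 15 to 16 weeks against 13 to 14 weeks. So did the genotype of the mice and the reporter of the sort. None of these, nor parabiosis, can be separated from the comparison.

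**Figure D1:**
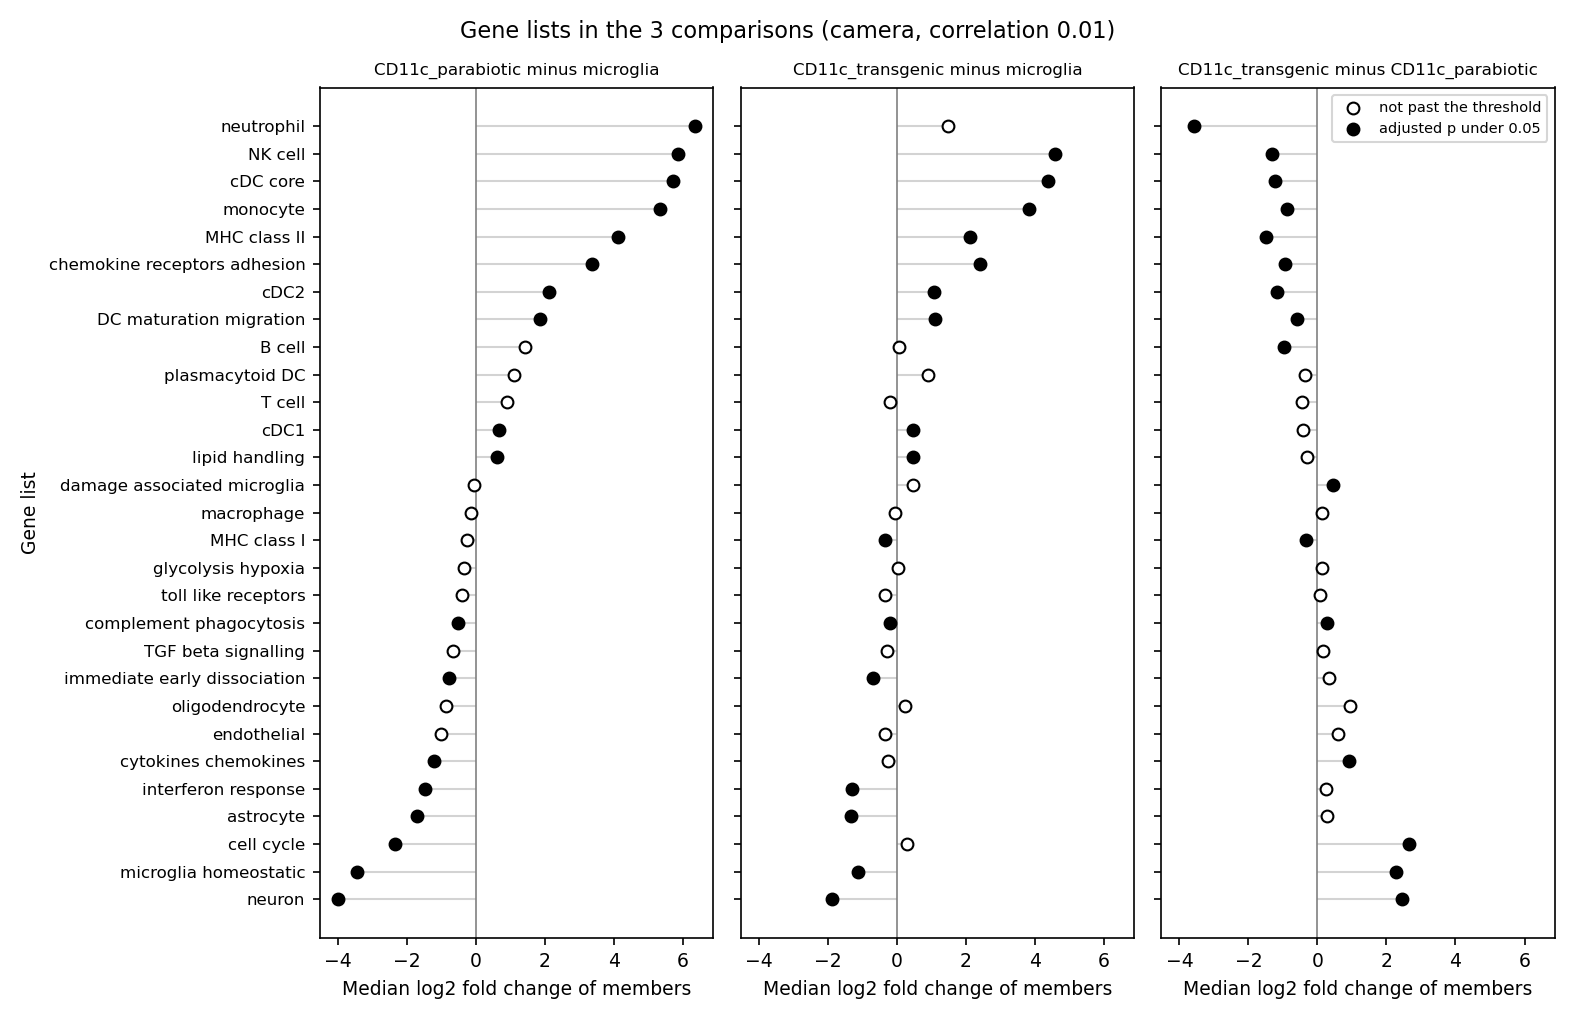
Median log2 fold change of the members of each of the 29 tested gene lists in the 3 comparisons, with filled points for lists that passed the camera test and open points for the others. The microglial list has a median of -3.44 in parabiotic CD11c cells against microglia and 2.27 in transgenic against parabiotic CD11c cells.

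The second comparison set CD11c-eYFP+ cells of the reporter mice themselves against microglia. Dendritic cell, MHC class II and monocyte genes were again higher, with smaller fold changes, microglial genes were lower by a smaller step, and cell cycle genes were not called. None of the lists that differed passed with an estimated correlation (adjusted p = 0.13 to 0.531). Flt3 stood at 55.9 ± 37 CPM against 1.3 ± 0.658 (5.42 ± 0.66, adjusted p = 0.000549, and 6.07 within the run, adjusted p = 1.38e-05). H2-Aa reached 1868 ± 972 against 31.7 ± 10.6 CPM (5.88 ± 0.50, adjusted p = 0.000101, and 6.40 within the run, adjusted p = 3.7e-06). P2ry12 fell from 1890 ± 269.7 to 602 ± 188 CPM (-1.65 ± 0.25, adjusted p = 0.00188, and -1.41 within the run, adjusted p = 0.0103). Sall1 stood at 104 ± 61.6 against 387 ± 75.3 CPM (-1.90 ± 0.46, adjusted p = 0.0227), a call that ended within the run (-1.35, adjusted p = 0.084). It also ended without microglia replicate 39 (adjusted p = 0.0999) or replicate 40 (adjusted p = 0.0709).

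Of the core dendritic cell genes, 20 of 25 members were higher, 0 were lower and 5 were not called. 21 were higher adjusted over the list alone (camera adjusted p = 1.45e-27, adjusted p = 0.201 with an estimated correlation, adjusted p = 3.09e-90 within the run with 23 members higher). Napsa was at 7.89 ± 0.52 (within the run 8.28), Slamf7 at 4.60 ± 0.37 (5.07) and Ccr7 at 4.63 ± 0.71 (5.38), while Zbtb46 was called only within the run (1.11 ± 0.51 pooled, adjusted p = 0.161, and 1.79, adjusted p = 0.00117). For cDC1 genes, 7 of 20 members were higher, 2 were lower and 11 were not called. 8 were higher and 3 were lower adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.531 with an estimated correlation, adjusted p = 2.81e-08 within the run with 9 members higher), with Xcr1 at 3.12 ± 0.67 (3.79) and Clec9a at 4.61 ± 0.94 (5.35). For cDC2 genes, 6 of 20 members were higher, 0 were lower and 14 were not called. 9 were higher and 1 was lower adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.442 with an estimated correlation, adjusted p = 4.15e-11 within the run with 9 members higher), with Cd209a at 4.95 ± 0.97 (5.77). In the maturation and migration list, 10 of 23 members were higher, 1 was lower and 12 were not called. 13 were higher and 3 were lower adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.405 with an estimated correlation, adjusted p = 4.47e-10 within the run with 12 members higher), with Ccl22 at 3.78 ± 0.45 (4.25). MHC class II genes were higher, as 8 of 13 members were higher, 0 were lower and 5 were not called. 9 were higher adjusted over the list alone (camera adjusted p = 5.97e-11, adjusted p = 0.201 with an estimated correlation, adjusted p = 1.12e-50 within the run with 9 members higher), with Cd74 at 5.03 ± 0.51 (5.61). MHC class I genes were lower, as 6 of 20 members were lower, 0 were higher and 14 were not called. 7 were lower adjusted over the list alone (camera adjusted p = 0.000393, adjusted p = 0.442 with an estimated correlation, adjusted p = 0.00542 within the run with 2 members lower), among them H2-Q6 at -1.80 ± 0.36 (-1.29). Left out singly, libraries ended the calls of Xcr1 (replicates 39, 40 or 41, adjusted p = 0.0515 to 0.0746), Clec9a (replicate 39, adjusted p = 0.0619) and Cd209a (replicate 39, adjusted p = 0.0515).

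Monocyte genes were higher, since 14 of 20 members were higher, 0 were lower and 6 were not called. 17 were higher adjusted over the list alone (camera adjusted p = 9.36e-19, adjusted p = 0.13 with an estimated correlation, adjusted p = 5.29e-33 within the run with 13 members higher), with Ccr2 at 5.38 ± 0.49 (5.96 within the run) and Ly6c2 at 6.96 ± 0.56 (7.20). In the chemokine receptor and adhesion list, 13 of 23 members were higher, 2 were lower and 8 were not called. 13 were higher and 3 were lower adjusted over the list alone (camera adjusted p = 2.84e-05, adjusted p = 0.212 with an estimated correlation, adjusted p = 3.87e-17 within the run with 12 members higher and 1 lower), and Itgb7 stood at 6.31 ± 0.71 (6.90). Lipid handling genes were higher, as 9 of 23 members were higher, 0 were lower and 14 were not called. 10 were higher and 1 was lower adjusted over the list alone (camera adjusted p = 0.000256, adjusted p = 0.201 with an estimated correlation, adjusted p = 0.00038 within the run with 8 members higher), including Lipa at 1.51 ± 0.23 (1.48). Of natural killer cell genes, 2 of 4 tested members were higher, 0 were lower and 2 were not called. 3 were higher adjusted over the list alone (camera adjusted p = 0.000182, adjusted p = 0.201 with an estimated correlation, adjusted p = 1.01e-10 within the run with 2 members higher), with Klrk1 at 6.43 ± 0.64 (6.996). Homeostatic microglial genes were lower, as 17 of 28 members were lower, 0 were higher and 11 were not called. 22 were lower adjusted over the list alone (camera adjusted p = 2.79e-13, adjusted p = 0.209 with an estimated correlation, adjusted p = 7.46e-10 within the run with 7 members lower), and Csf1r was at -1.23 ± 0.23 (-0.89). Interferon response genes were lower, as 10 of 24 members were lower, 0 were higher and 14 were not called. 18 were lower adjusted over the list alone (camera adjusted p = 1.09e-10, adjusted p = 0.385 with an estimated correlation, adjusted p = 8.67e-08 within the run with 3 members lower), and the signal transducer Stat2 stood at -1.55 ± 0.25 (-1.30). Immediate early genes were lower, as 6 of 22 members were lower, 1 was higher and 15 were not called. 9 were lower and 1 was higher adjusted over the list alone (camera adjusted p = 0.000215, adjusted p = 0.368 with an estimated correlation, adjusted p = 0.0105 within the run with 3 members lower and 1 higher), among them the transcription factor gene Jun at -1.39 ± 0.23 (-1.18). Complement and phagocytosis genes had a lower list value, as 5 of 29 members were lower, 3 were higher and 21 were not called. 7 were lower and 3 were higher adjusted over the list alone (camera adjusted p = 0.0411, adjusted p = 0.393 with an estimated correlation, adjusted p = 0.0589 within the run with 5 members lower and 2 higher), with the phagocytic receptor Mertk at -1.05 ± 0.15 (-0.88).

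For cell cycle genes edgeR called 0 of 28, with 0 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom (list median 0.31, camera adjusted p = 0.468, adjusted p = 0.229 within the run with 0 members called), and Mki67 stood at 108 ± 28.6 CPM against 109.8 ± 33.8. The cytokine and chemokine list did not pass pooled (5 higher, 8 lower and 28 not called of 41, camera adjusted p = 0.131). 13 were lower and 7 were higher adjusted over the list alone. It passed within the run (adjusted p = 0.0394), with Tnf at -1.33 ± 0.26 (-1.42 within the run), Il1a at -1.11 ± 0.18 (-1.05) and Ccl3 at -1.13 ± 0.20 (-1.18). The damage-associated microglia list was not called (5 higher, 3 lower and 16 not called of 24, camera adjusted p = 0.0849). 7 were higher and 3 were lower adjusted over the list alone. Gpnmb reached 2594 ± 602 CPM (4.84 ± 0.80, 4.61) and Clec7a 1.24 ± 0.22 (1.23). Spp1, at 4870 ± 2940 CPM in microglia and 20860 ± 15390 in the transgenic libraries, was not called (2.10 ± 0.65, adjusted p = 0.0539, 0.64). The plasmacytoid list was not called pooled (5 higher, 0 lower and 7 not called of 12, camera adjusted p = 0.515). 5 were higher and 3 were lower adjusted over the list alone. It passed within the run alone (adjusted p = 0.0116). Macrophage genes had a median of -0.04 against a mean of 0.36 and an upward test (7 higher, 2 lower and 11 not called of 20, camera adjusted p = 0.198). 7 were higher and 3 were lower adjusted over the list alone. Toll-like receptor genes were not called as a list (1 higher, 3 lower and 16 not called of 20, camera adjusted p = 0.174). 6 were lower and 1 was higher adjusted over the list alone. The same held for TGF-beta genes (3 higher, 4 lower and 13 not called of 20, camera adjusted p = 0.0923). 9 were lower and 3 were higher adjusted over the list alone. Glycolysis and hypoxia genes did not pass (2 higher, 3 lower and 17 not called of 22, camera adjusted p = 0.927). 3 were lower and 2 were higher adjusted over the list alone.

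Among markers of other cell types, astrocyte genes were lower than in microglia, as 2 of 9 members were lower, 0 were higher and 7 were not called. 5 were lower adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.368 with an estimated correlation, adjusted p = 0.015 within the run with 2 members lower), and Gfap stood at 5.62 ± 0.772 CPM. Neuronal genes were lower too, as 1 of 5 members was lower, 0 were higher and 4 were not called. 1 was lower adjusted over the list alone (camera adjusted p = 0.0261, adjusted p = 0.205 with an estimated correlation, adjusted p = 0.0338 within the run with 0 members called). Neutrophil genes did not pass (2 higher, 0 lower and 6 not called of 8, camera adjusted p = 0.0999). 3 were higher and 1 was lower adjusted over the list alone, and S100a8 stood at 5.33 ± 8.38 CPM. B cell genes did not pass either (1 higher, 0 lower and 7 not called of 8, camera adjusted p = 0.468). 1 was higher adjusted over the list alone. Igkc stood at 13.5 ± 8.25 CPM. T cell genes had a median of -0.20, a mean of 0.43 and an upward test (edgeR called 0 of 5, with 0 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.812). Oligodendrocyte genes had a median of 0.24, a mean of 0.02 and a downward test (0 higher, 1 lower and 7 not called of 8, camera adjusted p = 0.491). 1 was lower adjusted over the list alone. For endothelial genes edgeR called 0 of 10, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (camera adjusted p = 0.198).

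The 8 genes with the largest increase under the naming rule were Chil3 (chromosome 3, 106147554 to 106167564, 11.09 ± 1.49, within the run 8.79), B3gnt5 (9.17 ± 1.18, 8.97), Cdh1 (9.13 ± 0.98, 9.71), P2ry10 (chromosome X, 107088492 to 107104974, 8.14 ± 0.73, 8.41), Napsa (chromosome 7, 44572380 to 44586862, with the value above), the surface glycoprotein Cd24a (7.58 ± 0.60, 6.99), the orphan receptor Gpr171 (7.55 ± 0.67, 7.69) and the interleukin decoy receptor Il1r2 (7.48 ± 0.79, 7.84). Those with the largest decrease were the estrogen receptor Esr1 (chromosome 10, 4611593 to 5005614, -3.09 ± 0.40, -2.55), the tetraspanin Upk1b (-2.85 ± 0.56, -2.26), the adrenergic receptor Adrb1 (-2.75 ± 0.45, -2.38), C4b (chromosome 17, 34728380 to 34743882, -2.69 ± 0.27, -2.33), Crybb1 (-2.43 ± 0.48, -1.91), the myosin Myo18b (-2.40 ± 0.43, -1.92), the cadherin Cdh23 (-2.33 ± 0.49, -1.67) and the fructose transporter Slc2a5 (-2.20 ± 0.61). For Slc2a5 the call ended within the run (-1.55, adjusted p = 0.134). Chil3 varied from library to library, with 161 ± 227 CPM in the transgenic group. Left out singly, libraries ended the calls of Slc2a5 (replicates 15, 26, 39, 40 or 41, adjusted p = 0.0557 to 0.121), Cdh23 (replicates 39 or 40, adjusted p = 0.0516 to 0.0535), Crybb1 (replicate 39, adjusted p = 0.0509) and Upk1b (replicate 40, adjusted p = 0.0506).

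Across all genes, 2070 of 15151 (13.7%) differed between transgenic CD11c cells and microglia, 1345 higher and 725 lower, 1426 of them by at least 2-fold. The excess of higher genes depended on the method, with 1010 higher and 969 lower by limma-voom and 1186 and 860 under upper quartile scaling. The count was 3277 with DESeq2 and 1229 with only the 2 groups in the fit. Within the run the count was 1303, with 1023 higher and 280 lower, and 1091 genes were called in both fits. Libraries of the 2 groups did not overlap for 30.3% of tested genes, where chance gives 5.71%. Of 29 lists, 16 passed, 9 higher and 7 lower (17 within the run, 10 higher and 7 lower). With an estimated correlation camera called 0 (6 at an unadjusted p under 0.05, lowest adjusted p = 0.130, while fry called 14), and with the run term added it called 5, those for core dendritic cell genes, MHC class II, monocytes, chemokine receptors and natural killer cells. The count of genes fell to 746 without microglia replicate 39, to 775 without replicate 40 and to 1377 without replicate 41.

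The third comparison set the transgenic against the parabiotic CD11c cells, both sorted on the same reporter. Microglial genes, cell cycle genes and several cytokine genes were higher in the transgenic group, and dendritic cell, MHC class II and monocyte genes were lower as lists. With an estimated correlation none passed (adjusted p = 0.201 to 0.418). Sall1 stood at 104 ± 61.6 CPM in transgenic and 0.268 ± 0.122 in parabiotic CD11c cells (8.58 ± 0.74, adjusted p = 5.48e-05, and 9.13 within the run, adjusted p = 2.45e-05). Mki67 rose from 17.9 ± 0.475 to 108 ± 28.6 CPM (2.60 ± 0.26, adjusted p = 0.000161, and 2.40 within the run, adjusted p = 0.00046). Tnf rose from 27 ± 8.42 to 333 ± 88.2 CPM (3.62 ± 0.30, adjusted p = 4.98e-05, and 3.54 within the run, adjusted p = 0.000153). H2-Aa fell from 5745 ± 728 to 1868 ± 972 CPM (-1.62 ± 0.39, adjusted p = 0.0218, and -1.09 within the run, adjusted p = 0.0413). The H2-Aa call ended without parabiotic replicate 3 (adjusted p = 0.076), replicate 11 (adjusted p = 0.0511) or replicate 15 (adjusted p = 0.075).

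**Figure D2:**
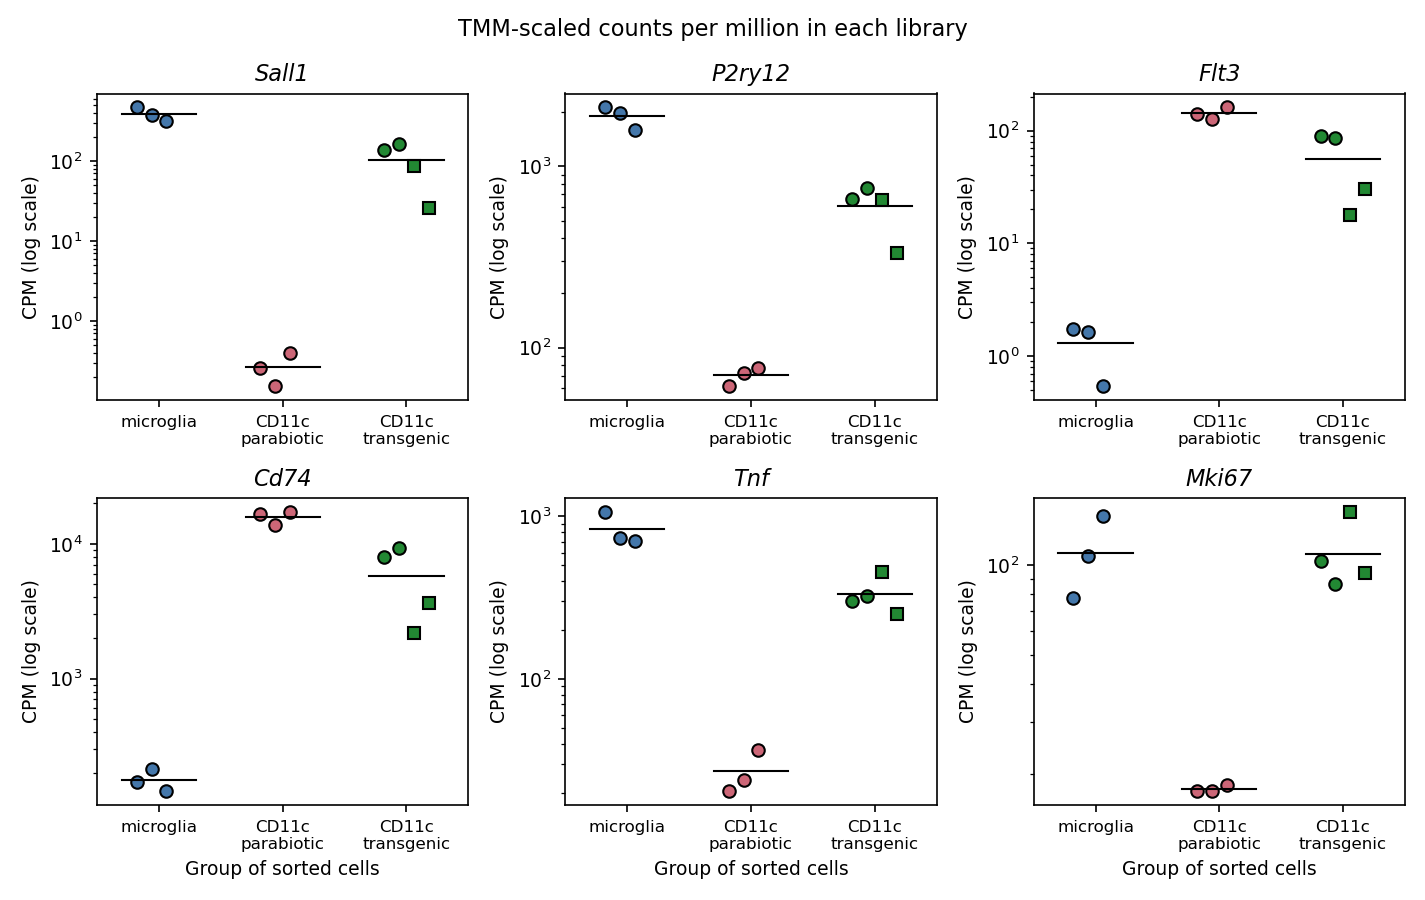
TMM-scaled CPM of 6 genes in each library on a log scale, with circles for libraries of the first run of library numbers, squares for transgenic replicates 26 and 27, and a line at the group mean. Sall1 has a mean of 387 CPM in microglia, 0.268 in parabiotic and 104 in transgenic CD11c cells.

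Of homeostatic microglial genes, 25 of 28 members were higher, 0 were lower and 3 were not called. 25 were higher adjusted over the list alone (camera adjusted p = 1.87e-33, adjusted p = 0.201 with an estimated correlation, adjusted p = 4.02e-44 within the run with 26 members higher). P2ry12 was at 3.10 ± 0.28 (within the run 3.34), Tmem119 at 1.47 ± 0.35 (1.75) and the Golgi protein Golm1 at 2.40 ± 0.19 (2.41). Among cell cycle genes, 27 of 28 members were higher, 0 were lower and 1 was not called. 27 were higher adjusted over the list alone (camera adjusted p = 5.57e-28, adjusted p = 0.201 with an estimated correlation, adjusted p = 1.78e-19 within the run with 23 members higher), with Kif11 at 2.68 ± 0.35 (2.40) and the ribonucleotide reductase subunit Rrm2 at 3.04 ± 0.43 (2.52). In the cytokine and chemokine list, 14 of 41 members were higher, 2 were lower and 25 were not called. 17 were higher and 4 were lower adjusted over the list alone (camera adjusted p = 2.01e-08, adjusted p = 0.201 with an estimated correlation, adjusted p = 3.2e-07 within the run with 13 members higher and 1 lower). Il1a was at 3.61 ± 0.21 (3.67), the growth factor Csf1 at 4.86 ± 0.42 (5.28), Ccl3 at 1.96 ± 0.21 (1.90) and Cxcl10 at 3.59 ± 0.59 (3.08), while Il1b was not called (-0.62 ± 0.21, -0.39). The damage-associated microglia list was higher, as 7 of 24 members were higher, 0 were lower and 17 were not called. 9 were higher adjusted over the list alone (camera adjusted p = 0.000119, adjusted p = 0.389 with an estimated correlation, adjusted p = 0.00149 within the run with 6 members higher), with Cst7 at 2.89 ± 0.45 (2.72). Complement and phagocytosis genes were higher, as 8 of 29 members were higher, 1 was lower and 20 were not called. 8 were higher and 2 were lower adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.387 with an estimated correlation, adjusted p = 0.0116 within the run with 7 members higher and 1 lower), including Pros1 at 2.41 ± 0.17 (2.40). With 1 library left out the call ended for Tmem119 (replicates 3 or 11, adjusted p = 0.0872 to 0.104).

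Core dendritic cell genes were lower as a list, as 4 of 25 members were lower, 0 were higher and 21 were not called. 11 were lower and 1 was higher adjusted over the list alone (camera adjusted p = 3.69e-08, adjusted p = 0.387 with an estimated correlation, adjusted p = 0.000613 within the run with 4 members lower), Napsa at -1.61 ± 0.34 (-1.22) and Slamf7 at -1.11 ± 0.30 (-0.64), while Flt3 (-1.36 ± 0.50, adjusted p = 0.119, -0.71) was not called. The cDC2 list was lower, as 1 of 20 members was lower, 0 were higher and 19 were not called. 0 passed adjusted over the list alone (camera adjusted p = 6.47e-05, adjusted p = 0.385 with an estimated correlation, adjusted p = 0.0176 within the run with 0 members called), while the cDC1 list was not called (1 higher, 1 lower and 18 not called of 20, camera adjusted p = 0.0999). 1 was higher and 1 was lower adjusted over the list alone. Maturation and migration genes were lower as a list, as 3 of 23 members were lower, 1 was higher and 19 were not called. 10 were lower and 2 were higher adjusted over the list alone (camera adjusted p = 0.00272, adjusted p = 0.418 with an estimated correlation, adjusted p = 0.132 within the run with 2 members higher and 2 lower). Ccl22 (-1.53 ± 0.37, -1.06 within the run with adjusted p = 0.054) and the costimulatory receptor Cd40 (-0.97 ± 0.22, -0.70 with adjusted p = 0.0508) were lower, and Ccr7 was not called pooled (-1.97 ± 0.58, -1.23). Of MHC class II genes, 7 of 13 members were lower, 0 were higher and 6 were not called. 10 were lower adjusted over the list alone (camera adjusted p = 2.79e-08, adjusted p = 0.205 with an estimated correlation, adjusted p = 8.14e-07 within the run with 7 members lower), and Ifi30 was at -0.68 ± 0.15 (-0.76). MHC class I genes passed the list test at a median of -0.33 with no single call (edgeR called 0 of 20, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.0354, adjusted p = 0.648 with an estimated correlation, adjusted p = 0.62 within the run with 1 member higher). Monocyte genes were lower, as 5 of 20 members were lower, 0 were higher and 15 were not called. 5 were lower adjusted over the list alone (camera adjusted p = 6.95e-06, adjusted p = 0.201 with an estimated correlation, adjusted p = 5.53e-05 within the run with 5 members lower), with Ccr2 at -1.39 ± 0.38 (-0.80) and Plac8 at -1.38 ± 0.36 (-0.84). The chemokine receptor and adhesion list was lower by its test although more members were called higher, as 2 of 23 members were higher, 1 was lower and 20 were not called. 4 were lower and 2 were higher adjusted over the list alone (camera adjusted p = 0.00808, adjusted p = 0.393 with an estimated correlation, adjusted p = 0.266 within the run with 2 members higher and 2 lower), with Icam1 at 1.69 ± 0.21 (1.95). Left out singly, libraries ended the calls of Ccr2 (replicates 3, 11, 15, 23, 26, 39, 40 or 41, adjusted p = 0.0503 to 0.134), Plac8 (replicates 3, 11, 15, 40 or 41, adjusted p = 0.0516 to 0.104), Slamf7 (replicates 3, 11, 15, 39, 40 or 41, adjusted p = 0.0583 to 0.121), Napsa (replicate 3, adjusted p = 0.0562), Cd40 (replicates 3 or 15, adjusted p = 0.0715 to 0.0841), Ccl22 (replicates 3 or 15, adjusted p = 0.0792 to 0.0904) and Ifi30 (replicates 3 or 15, adjusted p = 0.0611 to 0.0641).

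Neutrophil genes were lower in the transgenic group, as 3 of 8 members were lower, 0 were higher and 5 were not called. 7 were lower adjusted over the list alone (camera adjusted p = 0.00116, adjusted p = 0.205 with an estimated correlation, adjusted p = 0.0114 within the run with 1 member lower). The libraries overlapped, as the list mean in log2 CPM was 6.61 in parabiotic replicate 11, 4.735 in replicate 15 and 2.58 in replicate 3, against 2.71 in transgenic replicate 27 and 1.03 to 1.16 in the other transgenic libraries. B cell genes were lower, as 2 of 8 members were lower, 0 were higher and 6 were not called. 2 were lower adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.372 with an estimated correlation, adjusted p = 0.185 within the run with 0 members called), and Igkc was at -1.77 ± 0.49 (-1.20, adjusted p = 0.119 within the run). With 1 library left out the call ended for Igkc (replicates 3, 11, 23, 27, 39, 40 or 41, adjusted p = 0.0554 to 0.171). The natural killer list passed at a median of -1.32 without a single call (edgeR called 0 of 4, with 2 at an unadjusted p under 0.05, 2 called by DESeq2 and 2 by limma-voom, 2 were lower adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.405 with an estimated correlation, adjusted p = 0.129 within the run with 0 members called). Neuronal genes were higher, as 3 of 5 members were higher, 0 were lower and 2 were not called. 3 were higher adjusted over the list alone (camera adjusted p = 0.00746, adjusted p = 0.201 with an estimated correlation, adjusted p = 0.0236 within the run with 2 members higher). Their list median was 2.45, and 2.11 with the gene at 0 counts in the parabiotic group set to its bound. Interferon response genes were not called as a list (2 higher, 0 lower and 22 not called of 24, camera adjusted p = 0.684). 2 were higher adjusted over the list alone. Neither were astrocyte genes (2 higher, 0 lower and 7 not called of 9, camera adjusted p = 0.491). 2 were higher and 1 was lower adjusted over the list alone. Toll-like receptor genes did not pass (3 higher, 1 lower and 16 not called of 20, camera adjusted p = 0.536). 3 were higher and 2 were lower adjusted over the list alone. Nor did glycolysis and hypoxia genes (2 higher, 0 lower and 20 not called of 22, camera adjusted p = 0.515). 1 was higher adjusted over the list alone. Immediate early genes were not called pooled (3 higher, 0 lower and 19 not called of 22, camera adjusted p = 0.153). 3 were higher adjusted over the list alone, with adjusted p = 0.0352 within the run with 6 members higher and 1 lower. Plasmacytoid dendritic cell genes were not called (1 higher, 0 lower and 11 not called of 12, camera adjusted p = 0.491). 3 were higher and 1 was lower adjusted over the list alone. TGF-beta genes had a median of 0.17 and a mean of 0.08 against a downward test (3 higher, 1 lower and 16 not called of 20, camera adjusted p = 0.891). 3 were higher and 2 were lower adjusted over the list alone. Within the run they passed (median 0.44, 7 higher, 1 lower, adjusted p = 0.03, 0.241 with an estimated correlation). Lipid handling genes had a median of -0.31, a mean of 0.04 and a downward test (1 higher, 1 lower and 21 not called of 23, camera adjusted p = 0.0849). 2 were higher and 2 were lower adjusted over the list alone. Macrophage genes had a median of 0.13 and a mean of 0.27 against a downward test (1 higher, 1 lower and 18 not called of 20, camera adjusted p = 0.515). 1 was higher and 1 was lower adjusted over the list alone, with adjusted p = 0.0427 within the run with 3 members lower. No member was called for T cells (edgeR called 0 of 5, with 2 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.17), oligodendrocytes (edgeR called 0 of 8, with 4 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.462) or endothelial cells (edgeR called 0 of 10, with 1 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.786).

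Under the naming rule the largest increases were Sall1, Sall3 (chromosome 18, 80966376 to 80986771, 8.30 ± 0.60, within the run 8.71), Atp8a2 (6.995 ± 0.86, 7.67), the growth factor Tgfa (chromosome 6, 86195223 to 86275719, 6.81 ± 0.80, 7.17), the carbohydrate-responsive transcription factor Mlxipl (6.76 ± 0.65, 7.23), Nav3 (6.62 ± 0.76, 7.24), the matrix protein Sparc (chromosome 11, 55394500 to 55423183, 6.53 ± 0.56, 6.83) and the collagen receptor Mrc2 (6.41 ± 0.90, 7.02). The largest decrease was that of the neutrophil granule gene Ngp (chromosome 9, 110419747 to 110423012), with no count in the transgenic libraries and 72.2 ± 102 CPM in the parabiotic ones, at least 3693-fold lower against a floor of 3 counts over the transgenic group (adjusted p = 0.0126, and 0.0534 within the run). Ngp stood at 189 CPM in parabiotic replicate 11, 27.1 in replicate 15 and 0.316 in replicate 3. The lactoferrin gene Ltf (-7.59 ± 1.43, -7.04) had 56.6 ± 79.9 CPM in the parabiotic group. The others were the collagen-binding kinase Ddr1 (-2.56 ± 0.66, -1.78), Nxpe5 (-2.44 ± 0.62, -2.15), the interferon-induced Ifitm1 (chromosome 7, 140967221 to 140969825, -2.36 ± 0.53, -2.20), Igha (-2.27 ± 0.55, -1.56), the proteoglycan Gpc1 (-2.10 ± 0.38, -2.15) and H2-DMb2 (-2.00 ± 0.48, -1.30), which helps load peptides on MHC class II. Within the run the adjusted p was 0.112 for Nxpe5 and 0.074 for Ifitm1, so neither was called there. Left out singly, libraries ended the calls of Ddr1 (replicates 3, 11, 15 or 40, adjusted p = 0.0537 to 0.1), Nxpe5 (replicates 3, 11, 15, 23 or 26, adjusted p = 0.0556 to 0.101), Ifitm1 (replicate 3, adjusted p = 0.0676), Igha (replicates 3, 11 or 41, adjusted p = 0.0508 to 0.0959) and H2-DMb2 (replicates 3 or 15, adjusted p = 0.0781 to 0.083).

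The count over all genes was 1523 of 15151 (10.1%), 1156 higher and 367 lower in transgenic CD11c cells, 1192 of them by at least 2-fold, and 1619 within the run (1235 higher, 384 lower), with 1115 called in both fits. By limma-voom 967 were higher and 535 lower. The count was 2360 with DESeq2, 999 with only the 2 groups in the fit and 3482 without both libraries of the other run. Libraries did not overlap for 22.7% of tested genes (5.71% by chance). Of 29 lists, 16 passed, 6 higher and 10 lower (14 within the run, 8 higher and 6 lower), and with an estimated correlation camera called 0 both pooled (7 at an unadjusted p under 0.05, lowest adjusted p = 0.201, while fry called 12) and with the run term. The count of genes became 830 without parabiotic replicate 3, 897 without replicate 11, 905 without replicate 15 and 2510 without transgenic replicate 27. Age, the genotype of the mice and parabiosis, which only the parabiotic mice had undergone, cannot be separated from this comparison.

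To place the transgenic group between the other groups, the level of each list gene was expressed as a percent of a reference group. The 28 homeostatic microglial genes stood at a median of 46.4% of their microglia level in transgenic and 9.22% in parabiotic CD11c cells. By library the values were 50.7% and 54.7% in transgenic replicates 23 and 24, and 44.7% and 19.3% in replicates 26 and 27 (mean 42.3% ± 15.9, SD, n = 4), against 7.14%, 8.93% and 11.2% in the parabiotic libraries (9.07% ± 2.02, SD, n = 3). An exact two-sided permutation test of the list means gave p = 0.0286, the smallest that 35 splits allow, for a difference of 2.91 log2 units. The 25 core dendritic cell genes stood at a median of 42.5% of their parabiotic level in transgenic CD11c cells and 1.91% in microglia. By library they were at 66.5% and 62.8% in replicates 23 and 24, and at 13.9% and 24.2% in replicates 26 and 27 (41.8% ± 26.7, SD, n = 4), with an exact permutation p = 0.0857 for a difference of -1.39 log2 units. Taken by run, the group level was 52.7% for microglial and 64.3% for dendritic cell genes in replicates 23 and 24, and 31.4% and 20.2% in replicates 26 and 27. For cell cycle genes the exact two-sided permutation test between transgenic and parabiotic libraries gave p = 0.0286 for a difference of 2.23 log2 units. Across all genes, 1475 were called both between parabiotic CD11c cells and microglia and, with the opposite sign, between transgenic and parabiotic CD11c cells. The transgenic estimate lay between the other groups for 1242 of these, 528 of them also called against microglia, and beyond the microglia level for 233.

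**Figure D3:**
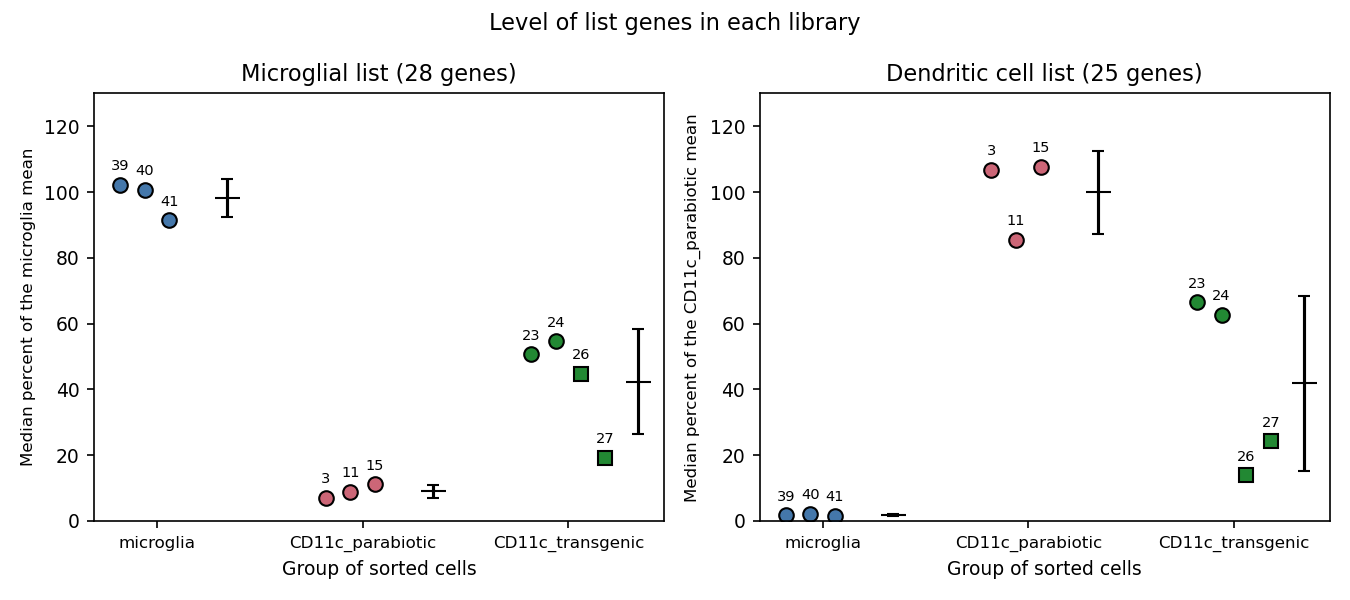
Median percent of the reference level over the 28 microglial genes (reference microglia) and the 25 dendritic cell genes (reference parabiotic CD11c cells) in each library, numbered by replicate, with mean and SD per group at the side and squares for transgenic replicates 26 and 27. Microglial genes lie between 19.3% and 54.7% in the transgenic libraries and between 7.14% and 11.2% in the parabiotic ones.

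Both CD11c groups were compared with the same 3 microglia libraries, so their calls share chance values. Of the calls in the transgenic group, 1942 (93.8%) were called in the same direction in the parabiotic group, 1248 higher and 694 lower, where 364 would be shared by independent lists of these sizes, a value that leaves out the shared microglia. In 20 simulations of unchanged groups against shared microglia, which leave out the effects, 0 were shared. Across genes the fold changes of the 2 comparisons had a correlation of 0.832 against 0.539 in the simulations and a covariance of 1.91 against 0.105, and genes are not independent replicates. The 3 microglia libraries could not be divided so that each comparison had at least 2 of its own, and part of the excess may come from them. The shared count became 741 without microglia replicate 39 and 771 without replicate 40. The single gene called in opposite directions was Gdf15, a stress-induced cytokine, at 84.7 CPM in microglia, 130 in parabiotic and 54.6 in transgenic CD11c cells.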

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

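All explanations weighed in this part were tested only after the results they concern had been seen, and so were the counts over other splits of the libraries.

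Transgenic CD11c cells carried microglial genes at 46.4% of the microglia level and dendritic cell genes at 42.5% of the parabiotic level. A candidate explanation is that both kinds of cell were sorted and their RNA mixed. In replicates 23 and 24 the median shares, 44.1% from microglial and 64.0% from dendritic cell genes, added up to 108%. That exceeds the whole of such a mixture, which stays open there. The shares added up to 43.1% in replicate 26 (32.3% and 10.8%) and 29.7% in replicate 27 (7.61% and 22%), which argues against a mixture of the 2 measured populations alone there. Cell cycle genes in replicates 23 and 24 lay above the level of the mixture. The median ratio was 1.62 (quartiles 1.44 to 1.77, 27 of 28 genes above). Their list means in microglia ranged from 4.96 to 5.86 log2 CPM, so the ratio settles nothing. Another population, such as microglia that express CD11c, and a difference between the library runs stay open.

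The parabiotic CD11c cells kept counts of microglial genes at a median of 9.22% of the microglia level, and microglia among the sorted cells or reads of microglia libraries could have brought them. Either would place all members at about the same percent, but the members ranged from 0.0694% for Sall1 to 67.9% for Trem2, and the median was 32.3 times the 10th percentile of 0.285%. Reads moved between all libraries alike are argued against by Sall1, Nav3 and Serpine2, whose mean of 0.686% was 7.44% of the list median. Expression of part of the list by the infiltrating cells themselves stays open as a hypothesis.

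Neutrophil genes were high in parabiotic replicate 11, with S100a8 at 202 against 5.05 CPM in replicate 3, S100a9 at 209 against 0.172 CPM and Ngp at 189 against 0.316 CPM, and replicate 15 held S100a9 at 12% and Ngp at 14.3% of the level in replicate 11. The sort used the reporter without antibody staining, so neutrophils among the sorted cells were weighed with 12 neutrophil genes outside the list. Their median ratio of unscaled CPM in replicate 11 to replicate 3 was 3.45 (quartiles 1.80 to 9.22, 10 of 12 above 1), between the ratio over 5 expected with neutrophils and that under 2 expected without, so this explanation stays open. The list's call against microglia did not rest on replicate 11, since without it the camera adjusted p was 0.00766, although without transgenic replicate 27 it was 0.0528. No biological explanation was tested, as the labels give none for a single library.

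For parabiotic CD11c cells against microglia the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 5347 genes and 18 lists, and the highest other 0 genes (edgeR, adjusted) and 15 lists. For transgenic CD11c cells against microglia only the real split of 35 gave as many as 2070 genes. The highest other, the 3 microglia with transgenic replicate 26, gave 393. For transgenic against parabiotic CD11c cells only the real split gave as many as 1523. The 3 parabiotic libraries with transgenic replicate 27 gave 1086. In both, 6 of 35 splits gave as many as the 16 lists, up to 18, so chance is not excluded for lists. 1 of 35 is the lowest share possible, and splits cannot tell group from run or age.

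In the group of 4 transgenic libraries, 15 of 134 values examined (11.2%) had 1 library far from the other 3, where chance picks about 1 in 20. All lay in replicates 26 (9 values) and 27 (6 values). Replicate 26 had 35.1% of its counts in its 100 most abundant genes (28.4% to 29.2% in the others). Its list means in log2 CPM were 10.25 for damage-associated microglia genes (9.57 to 9.63 in the others) and 6.46 for cell cycle genes (5.23 to 5.32). Its log2 CPM was 6.29 for the mitotic kinesin Kif11 (5.27 to 5.36) and 7.40 for Rrm2 (5.84 to 6.00), and lower than in the others for Il1r2 at 4.45 (7.56 to 7.67), P2ry10 at 4.18 (6.58 to 6.82), Tlr8 at 5.26 (5.57 to 5.58) and Vegfa at 6.02 (7.56 to 7.70). Replicate 27 had a neutrophil list mean of 2.71 (1.03 to 1.16) and Cd24a at 6.97 (5.14 to 5.38), and lower values for the glutamate transporter Slc1a3 at 3.67 (5.22 to 5.52), Sparc at 8.79 (10.30 to 10.47), Tmem119 at 8.11 (9.503 to 9.70) and Tgfa at 4.31 (6.06 to 6.35).

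The effect against microglia differed between the CD11c groups for the cell cycle list, lower in parabiotic CD11c cells and not called in transgenic ones, with a tested difference of 2.64 in the list median (camera adjusted p = 5.57e-28). With an estimated correlation the adjusted p of this difference was 0.201, and 0.239 with the run term as well, and that of the lower level in parabiotic CD11c cells was 0.389. The effect against microglia also differed in sign for Gdf15, where transgenic minus parabiotic CD11c cells gave a log2 fold change of -1.25.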

How the results depend on the processing

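2 alternatives were added after the data had been seen, leaving out both transgenic libraries of the other run, and the run term with an estimated correlation. Comparisons are called A (parabiotic against microglia), B (transgenic against microglia) and C (transgenic against parabiotic). The counts of genes stayed within 1.5 times 5347, 2070 and 1523 under RLE and upper quartile scaling, limma-voom, both filters, thinned counts, non-robust dispersion and the 2-fold minimum. Upper quartile scaling put the median of all genes in A at -0.10. In B and C DESeq2 gave 3277 and 2360 genes, and a fit of only the 2 groups 1229 and 999. The run term gave 1303 in B. Without both libraries of the other run A had 8334 genes and C 3482. The cause was not tested for any of these.

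With an estimated correlation camera called 0, 0 and 0 lists in A, B and C, where 7, 6 and 7 had an unadjusted p under 0.05 and fry called 21, 14 and 12. With the run term as well it called 4, 5 and 0, and the cause was not tested. With 1 library left out, genes in A ranged from 3747 to 6458. In B they ranged from 746 (without microglia replicate 39) to 2684. In C they ranged from 830 (without parabiotic replicate 3) to 2510 (without transgenic replicate 27). Lists ranged from 16 to 20 in A, 14 to 18 in B and 15 to 18 in C. Shared calls ranged from 741 (without microglia replicate 39) to 2200. Microglial gene levels ranged from 40.8% to 53.2% and dendritic cell gene levels from 33.5% to 51.2%.

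Among values of named genes with 1 library left out, 2078 kept their direction and side of the threshold, 123 lost the call and 6 gained one. The run term ended 11 calls and added 3. Most calls lost are given beside the genes, and of 14 alternatives for each gene the call also ended in B for Egr1 in 3, Apoe in 2, Vegfa in 1 and in C for Il1r2 in 9, Rab7b in 6, Lyz2 in 1. The genes in A that were not called and changed sign with 1 library left out were Batf3 (-0.22 to 0.17) and Il12b (-0.83 to 0.0561). No paired analysis was possible because the groups share no replicate numbers. Thinned to the smallest total, the counts were 5352, 2088 and 1514 genes.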

Other observations

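Further genes named in advance complete the account. Arg1, an enzyme of arginine breakdown in alternatively activated myeloid cells, was higher than in microglia in both CD11c groups, at 122 ± 84 CPM in parabiotic and 98.3 ± 178 in transgenic against 1.45 ± 0.309 in microglia (6.39 ± 1.65, adjusted p = 0.0114, and 6.08 ± 1.61, adjusted p = 0.0307), and within the run the second value was 2.62 (adjusted p = 0.231). The transgenic level rested on replicate 27, where log2 CPM of Arg1 was 8.51 against 2.28 to 3.70 in the other 3, and without transgenic replicate 27 the fold change was 2.69 (adjusted p = 0.00907). The transgenic call of Arg1 ended without microglia replicate 39, 40 or 41 (adjusted p = 0.13, 0.121 and 0.0948). The chemokine gene Ccl5 was higher in parabiotic CD11c cells (1.05 ± 0.32, adjusted p = 0.0245), while Cxcl9 (0.38 ± 0.49) and Il12b (-0.43 ± 0.60), which encodes a cytokine subunit that promotes T helper responses, were not called. C1qa, a chain of the first complement component, stood at 3662 ± 431 CPM in microglia, 1374 ± 355 in parabiotic (-1.41 ± 0.28, adjusted p = 0.00262) and 2665 ± 843 in transgenic CD11c cells. Tlr3, a sensor of double-stranded RNA, was lower in parabiotic CD11c cells than in microglia (-2.60 ± 0.47, adjusted p = 0.00157), and Tlr9 was not called (-1.30 ± 0.47, adjusted p = 0.0524). Tgfb1 was lower (-0.61 ± 0.17, adjusted p = 0.0179), and the growth factor gene Flt3l (-0.38 ± 0.40) and the dendritic cell regulator Id2 (-0.11 ± 0.33) were not called. Left out singly, libraries ended the calls of Ccl5 (replicates 11, 15, 39 or 40, adjusted p = 0.064 to 0.0777) and Tgfb1 (replicates 3, 11, 15 or 40, adjusted p = 0.0588 to 0.0633).

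2 genes stood out in the transgenic group by library run and were chosen after their values were seen. The protocadherin Pcdhga12 reached 92.1 and 151 CPM in replicates 26 and 27 and at most 2.79 in any other library. The immunoglobulin heavy chain gene Ighg2c stood at 4.13 and 4.45 CPM in replicates 23 and 24 and at most 0.517 in any other library.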
